A study of Mus musculus with 9 samples.

How the data were processed

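RNA was sequenced from 9 libraries of mouse cells labelled LT-HSCs (long-term hematopoietic stem cells), 3 libraries in each of 3 groups: Control, 5-FU+Saline and 5-FU+FMT. Per the labels, the cells were sorted as lineage-negative, Sca1-positive, c-Kit-positive and CD150-positive, with a last marker written C48-, which is read here as CD48-negative. Total RNA was isolated with Trizol, libraries were made with a NEBNext Ultra II kit and read in pairs on an Illumina NovaSeq, per the labels. The labels say neither whether a library came from 1 mouse or from several, nor which sex the mice had, and they do not spell out FMT.

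The deposited values are read counts per gene, with a file for each library. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.5, aligned to mm10 with HISAT2 2.2.1, handled with SAMtools and counted with featureCounts 2.0.1. Per the file headers, featureCounts counted read pairs over exons, summed by gene, with the GENCODE M25 annotation, from alignments whose name says sorted and unique. The headers show no strand option, so genes that overlap on opposite strands, such as Xist and its antisense neighbour, cannot be separated. They show no option for multiply mapped reads either, so the levels of near-identical genes (the Hspa1a and Hspa1b pair, alpha and beta globins, immunoglobulin V segments, ribosomal proteins and their pseudogenes) are uncertain gene by gene.

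Each table lists 56262 genes, and 55141 IDs were given a symbol and 55227 a biotype from reference tables, with the ID version ignored; the biotypes come from another GENCODE release than the counts. Coordinates are those of the count tables, on mm10. Symbols such as Atp5b and Atp5c1 are those of the reference table.

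Everything from here on was computed from the deposited counts. Genes were filtered with filterByExpr, which left 16595 genes, and libraries were scaled by TMM. Levels are CPM, the counts divided by TMM-scaled library size. The 3 groups were fitted together in edgeR 4.0.16 (quasi-likelihood F test, limma 3.58.1, R 4.3.3, with the package data.table in version 1.17.8), and the 3 comparisons were 5-FU+Saline against Control, 5-FU+FMT against 5-FU+Saline and 5-FU+FMT against Control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All adjusted p-values of single genes in the text are from this edgeR test with this adjustment unless another tool is named. Folds and log2 fold changes are fitted values. Means and SDs are of CPM over the libraries of a group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

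The groups, the comparisons, the 38 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists were LT-HSC identity, sort gate markers, quiescence and cell cycle inhibitors, immediate early genes, DNA replication, mitosis, p53 targets, DNA repair, type I interferon response, MHC class I and class II presentation, NF-kB and inflammatory response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, glycolysis, antioxidant genes, iron handling, fatty acid oxidation, cholesterol synthesis, ribosome biogenesis and MYC targets, the unfolded protein and integrated stress response, autophagy and lysosome, apoptosis regulators, TGF-beta and BMP signalling, adhesion and homing, JAK-STAT targets, multipotent and lymphoid-primed progenitors, cytosolic ribosomal proteins, and markers of megakaryocytes, erythroid cells, neutrophils, monocytes and macrophages, dendritic cells, mast cells and basophils, B cells, T and NK cells, endothelium and stroma. Each list was tested with camera in limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 38 lists of a comparison. Camera compares the test statistics of a list's genes with those of the other genes. It was repeated with a correlation estimated per list, a stricter test. List p-values in the text are at the preset correlation unless the estimated one is named. Where the genes of a list vary together, the preset p-values can be too small by many orders of magnitude.

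The rule for naming genes took, per comparison and direction, the 10 called genes with the largest fitted fold among those with at least 10 CPM in a group, a standard symbol and no overlap between the libraries of both groups. It added Kit, Ly6a, Slamf1, Cd48, Procr, Hlf, Mecom, Cdkn1a and Mki67 in every comparison, and up to 4 members per list with the smallest p, a pair in each direction where both moved. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. A fold against a group with no count is given as a lower bound from 3 counts over the group's libraries. A fold against 1 to 3 counts is given as the ratio with its 95% counting interval. Such intervals and bounds cover counting error only.

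The fit was tested on simulated counts with 200 changed genes per comparison, 50 per fold size. Of genes changed 2-fold, 80% were called in 5-FU+Saline against Control (16262 genes tested), 76% in 5-FU+FMT against 5-FU+Saline (16287 genes) and 66% in 5-FU+FMT against Control (16274 genes). At 1.5-fold these shares were 60%, 64% and 74%, at 1.25-fold 42%, 60% and 42%, and at 1.1-fold 12%, 6% and 10%, and false calls made up 3.96%, 5.51% and 1.03% of all calls. Far more than 200 genes were called in the data, which loosens the adjusted threshold. The shares therefore do not give the detection rates of the comparisons. In simulated counts of 5-FU+FMT against 5-FU+Saline, camera called 5 of 5 lists moved 1.2-fold and 0 of 15 unchanged lists.

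Whether replicate numbers pair libraries across groups was checked by correlating each library's residuals from its group mean. Same-number pairs gave r from -0.0173 to 0.0194 (9 pairs) and other pairs from -0.0296 to 0.0281 (18 pairs), so no pairing was used. The position of the 5-FU+FMT group was computed from mean CPM on a linear scale with Control at 0 and 5-FU+Saline at 1, for genes of at least 5 CPM, with medians bootstrapped over genes 2000 times. Opposite movement was measured on a 5-FU+Saline library left out of the calls, and changes shared against Control were set beside 20 simulated draws with no true change.

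The alternatives fixed in advance were DESeq2 1.42.0, limma-voom with sample weights, RLE or upper-quartile factors, no filter, a stricter filter of at least 5 CPM in 3 libraries, the 6 compared libraries alone, a replicate block, each library left out in turn, and camera with an estimated correlation. A pair was chosen after seeing the data: glmTreat against a change of at most 1.5-fold, and counts without immunoglobulin and sex chromosome genes. The raw reads, splicing and sequence variants were not analysed here.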

Results

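RNA was measured in cells of C57BL/6 mice sorted as LT-HSCs, the rare bone marrow cells that sustain blood formation over the long term. Control mice were untreated. Mice of both other groups received 5-FU (5-fluorouracil, a drug that kills dividing cells) at 250 mg/kg, followed by saline, which the series text calls PBS, or by FMT, an agent the labels do not spell out, given intravenously at 5 mg/kg on days 1, 4 and 7. The cells of treated mice were taken on day 8, and the schedule of the saline is not stated. Each group held 3 libraries. Total counts were 13653663, 11098031 and 19095358 in Control replicates 1 to 3, 15128336, 15606275 and 19270976 in 5-FU+Saline, and 15435644, 14089347 and 13723506 in 5-FU+FMT. Each library detected between 22813 and 24237 genes.

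The 3 groups stood far apart. The first principal component held 69.5% of the variance and placed Control between -65.8 and -63.7, 5-FU+FMT between 0.822 and 4.25, and 5-FU+Saline between 61.7 and 62.0. The second held 7.89% and set 5-FU+FMT (-25.8 to -23.3) apart from all other libraries (9.02 to 13.9). Spearman correlations across genes were 0.993 to 0.994 within groups (9 pairs) and 0.947 to 0.983 between groups (27 pairs). Counts of a pair of libraries differed by a chi-square per degree of freedom of 2.15 to 2.57 within groups and 24.3 to 133 between groups, and the biological coefficient of variation was 3.74%. Nothing in the labels says that the libraries of a group are separate mice, so the p-values may measure technical spread only. Sex-linked RNA, given below, argues against a single mouse per treated library if it marks the sex of the cells.

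**Figure D1:**
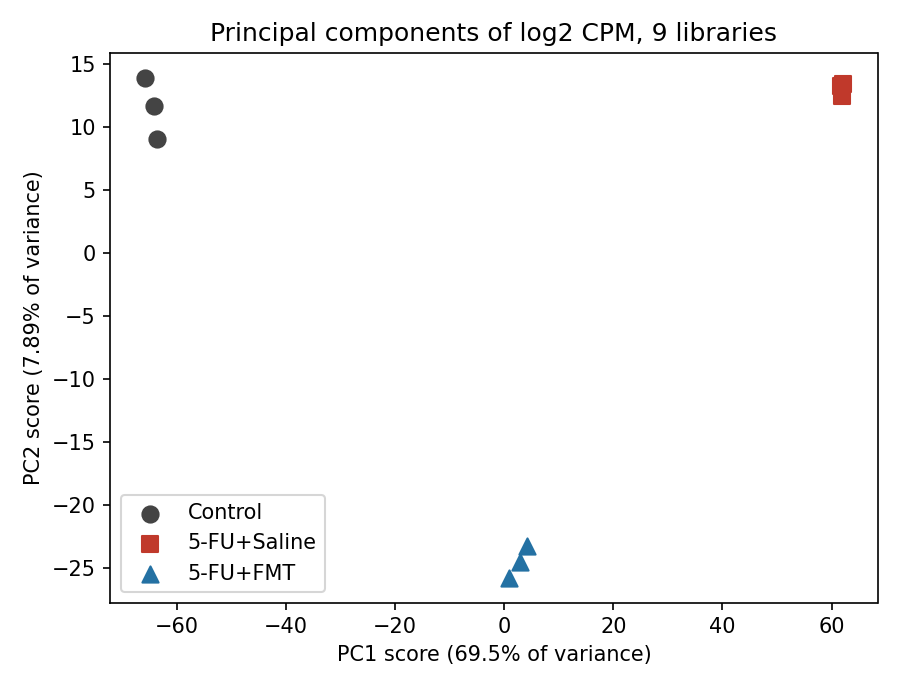
Scores of the 9 libraries on the first and second principal component of log2 CPM, with the share of variance on each axis. The 3 groups separate along the first component, which holds 69.5% of the variance, with 5-FU+FMT between the other groups.

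Several features of the libraries moved with the groups. Xist, the RNA that silences an X chromosome in female cells (X, 103460366 to 103483254), had 0.870 ± 0.421 CPM in Control, 1201 ± 20.2 in 5-FU+Saline and 682 ± 19.8 in 5-FU+FMT (SD, n = 3). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, chosen after their values were seen, lay in 5-FU+Saline at 29.03% ± 4.72 and in 5-FU+FMT at 65.4% ± 6.05 of their Control level (SD over 4 genes). Control thus held almost no Xist, while both treated groups held Xist and Y-linked RNA side by side. Every comparison below therefore also sets groups of different sex-linked RNA against each other. Effects of treatment and of sex composition cannot be told apart in these libraries. Immunoglobulin genes took 3.20% ± 0.0394 of the counts in Control, 1.81% ± 0.0235 in 5-FU+Saline and 2.18% ± 0.0455 in 5-FU+FMT. Igha, the heavy chain of IgA antibodies, also chosen after its values were seen, was at 9654, 5956 and 6559 CPM. Ribosomal and small RNAs took 1.11% ± 0.0397, 0.149% ± 0.0128 and 0.485% ± 0.0419, and mitochondrial genes 1.13%, 1.21% and 1.17%.

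The first comparison, 5-FU+Saline against Control, sets cells sorted as LT-HSCs 8 days after 5-FU beside those of untreated mice. Immediate early genes, which cells switch on within minutes of a stimulus, were far lower. Fosb fell from 6149 ± 36.6 to 577 ± 9.28 CPM (10.7-fold), Klf6 from 1712 ± 14.4 to 161 ± 0.856 (10.6-fold), Jun from 4009 ± 7.80 to 404 ± 9.29 (9.93-fold) and Egr1 from 2447 ± 15.1 to 247 ± 7.43 (9.90-fold, SD, n = 3). By level, Fosb and Jun ranked 4 and 9 among all genes in Control. Whether 5-FU or another difference between the groups, such as in how cells were handled, set these levels was not tested. Proliferation genes were higher: Mki67, a protein of dividing cells (7, 135689784 to 135716361), rose from 443 ± 15.01 to 991 ± 10.01 CPM, and Top2a, which untangles replicated DNA, rose from 359 ± 2.01 to 923 ± 19.5. Most erythroid genes were lower, as was the granule peroxidase gene Mpo, which fell from 1277 ± 0.836 to 29.9 ± 1.14 CPM, while most genes of the B lineage and stromal lists were higher.

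Of 16595 genes tested, 5443 were higher and 5429 lower in 5-FU+Saline (65.5% of all), 1081 and 1852 of them by at least 2-fold. CPM of the 3 and 3 libraries did not overlap for 67.8% of genes, against 10% by chance. Of the 38 lists, 9 were higher and 13 lower by camera, and 6 and 6 with an estimated correlation.

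All 24 mitosis genes rose, with a median log2 fold change of 1.24 (camera adjusted p = 3.76e-38, adjusted p = 0.00572 with an estimated correlation). Among them was Ccnb1, which drives entry into mitosis (3.25-fold). All 24 DNA replication genes rose (median 0.89, adjusted p = 7.45e-23), such as the replication regulator Uhrf1 (2.67-fold), Rrm2 (3.01-fold) and Rrm1 (2.15-fold), subunits of the enzyme that makes deoxynucleotides, and Mcm5 (1.98-fold), part of the replicative helicase. Of 25 DNA repair genes 23 rose (median 0.74, adjusted p = 1.6e-07), including Parp1 (1.82-fold), Rad51ap1 (2.37-fold) and Brca1 (2.04-fold), which act at DNA breaks. All 24 nuclear-encoded oxidative phosphorylation genes rose (median 0.66, adjusted p = 1.59e-10, adjusted p = 0.0581 with an estimated correlation), such as the ATP synthase subunit Atp5b, from 751 ± 11.99 to 1324 ± 2.15 CPM, and Cyc1 of complex III (1.75-fold). Of 17 glycolysis genes 14 rose and 3 fell (median 0.45, adjusted p = 1.35e-05, adjusted p = 0.0581 with an estimated correlation): Ldha, which makes lactate, and Pgk1 rose 2.05-fold and 2.01-fold, while the glucose transporter Slc2a3 fell 1.71-fold and Pdk1, a brake on pyruvate use, fell 1.18-fold. Of 22 ribosome biogenesis genes and MYC targets 20 rose and 2 fell (median 0.46, adjusted p = 1.32e-06), with Cad (1.87-fold) and Npm1 (1.62-fold) higher and Myc itself 1.30-fold lower. The other, Odc1, fell 1.05-fold (adjusted p = 0.0254), and its call was lost without 5-FU+Saline replicate 2 (0.0787), without 5-FU+Saline replicate 3 (0.176), without Control replicate 3 (0.113) and with DESeq2 (0.162), RLE factors (0.0566) or no filter (0.546).

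All 20 immediate early genes fell (median -2.46, camera adjusted p = 3.07e-159). With the estimated correlation of 0.396 the adjusted p was 0.00195. Of 17 quiescence and cell cycle inhibitor genes 5 rose and 10 fell (median -0.46, adjusted p = 6.63e-15). That list shares Egr1, Nr4a1 (4.09-fold lower) and Btg2 with the immediate early genes, while Foxo1, a transcription factor of resting cells, rose 2.01-fold and Cdkn2d 1.44-fold. The heat shock genes Hspa1b (17, 34956436 to 34959238) and Hspa1a fell from 304 ± 3.42 to 2.05 ± 0.329 and from 126 ± 0.967 to 0.959 ± 0.0873 CPM. Of 22 NF-kB and inflammatory genes 5 rose and 12 fell (median -0.39, adjusted p = 9.41e-08). The chemokine Ccl3 (11, 83647844 to 83649355) fell from 108 ± 1.64 to 0.594 ± 0.247 CPM and the regulator Nfkbiz fell 3.29-fold, while Nfkb1 and Myd88 rose 1.21-fold and 1.36-fold. Of 18 genes of the unfolded protein and integrated stress response 2 rose and 12 fell (median -0.40, adjusted p = 2.13e-05, adjusted p = 0.0552 with an estimated correlation): the chaperone Hspa5 fell from 1652 ± 12.4 to 575 ± 16.6 CPM and Atf4 2.14-fold, while Pdia3 and Pdia6 rose 1.31-fold and 1.16-fold.

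Stem and progenitor genes moved apart. Of 25 LT-HSC identity genes 6 rose and 16 fell (median -0.27, camera adjusted p = 0.0408, adjusted p = 0.127 with an estimated correlation), and the call was lost without 5-FU+Saline replicate 2 (adjusted p = 0.0560) and with the stricter filter (0.0526). Hlf (11, 90336536 to 90390895) fell from 565 ± 6.93 to 243 ± 3.07 CPM, while Vwf rose 3.14-fold, Esam 1.83-fold and Mecom 1.31-fold. Procr fell 1.21-fold. Of 8 measured sort gate genes 4 rose and 4 fell (adjusted p = 0.753). Kit (5, 75574916 to 75656722) fell from 754 ± 6.41 to 411 ± 7.08 CPM, Slamf1, which encodes CD150 (1, 171767127 to 171801184), rose from 8.35 ± 1.16 to 34.6 ± 2.06, Cd48 (1, 171682009 to 171705258) rose from 30.7 ± 1.27 to 53.7 ± 0.558, and Ly6a, the Sca1 gene, rose 1.21-fold. RNA of Cd48, the negative gate, thus stood above that of Slamf1, a positive gate, in every group (46.7 and 24.4 CPM in 5-FU+FMT). In Control, Flt3 and Mpo stood at 585 and 1277 CPM, far above Slamf1. These RNA levels do not bear out the sort label, and whether the groups held the same kinds of cell was not tested. Cdkn1a, a p53 target that blocks the cell cycle, had 93.2 ± 0.652 and 93.5 ± 4.44 CPM (adjusted p = 0.936). Of 16 genes of multipotent and lymphoid-primed progenitors 4 rose and 11 fell (median -0.999, adjusted p = 2.88e-10). Flt3, a receptor of early progenitors, fell from 585 ± 8.82 to 70.9 ± 2.47 CPM and Ctla2a 3.07-fold, while the antigen receptor recombinase genes Rag1 and Rag2 rose 34.4-fold and 11.03-fold.

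Of 18 erythroid genes 1 rose and 15 fell (median -3.33, camera adjusted p = 1.14e-17). Car1, a carbonic anhydrase (3, 14766216 to 14808368), fell from 221 ± 4.12 to 1.99 ± 0.646 CPM, Ermap from 103 ± 5.71 to 0.805 ± 0.364 and Kel from 29.8 ± 3.16 to 0.373 ± 0.223. Hbb-bt, a beta globin, rose 3.32-fold. The near-identical Hbb-bs and the alpha globin Hba-a1, chosen after their values were seen, were at least 4-fold lower. The rise of Hbb-bt is therefore uncertain and does not show that beta globin RNA rose. Slc4a1, the red cell anion exchanger, and Pklr, the red cell pyruvate kinase, were at 19.8 and 39.6 CPM in Control and at 0.0857 and 0.188 in 5-FU+Saline. The ratio of Control to 5-FU+Saline counts for Slc38a5 was 230.4 (95% interval 78.5 to 1121), and Btnl10 was at least 176-fold lower. Of 17 neutrophil genes 8 rose and 8 fell. The median was 0.19 and the mean -0.52, and camera put the list lower (adjusted p = 1.73e-17). The granule gene Mpo fell 42.6-fold, from 1277 CPM, and the elastase gene Elane (10, 79886247 to 79888215) from 397 ± 5.72 to 5.02 ± 0.746 CPM. Ltf rose 45.7-fold and Ngp 10.5-fold, but only from 0.200 to 8.86 and from 0.87 to 8.45 CPM. Of 13 mast cell and basophil genes 2 rose and 10 fell (median -1.23, adjusted p = 0.00556, adjusted p = 0.0873 with an estimated correlation): the proteases Prss34 and Mcpt8 fell 46.2-fold and 15.4-fold, while Tpsb2 and Cma1 rose 2.84-fold and 2.27-fold.

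Several B lineage genes rose from under 1 CPM in Control. Of 17 B cell genes 13 rose and 3 fell (median 2.79, camera adjusted p = 1.88e-24, adjusted p = 0.0131 with an estimated correlation). Pax5, which commits cells to the B lineage (4, 44524757 to 44710487), rose from 0.501 ± 0.154 to 142 ± 2.99 CPM, Igll1, part of the pre-B cell receptor (16, 16860671 to 16863985), from 0.308 ± 0.221 to 149 ± 4.89, Vpreb1 263-fold and Ebf1 118-fold. The ratio of 5-FU+Saline to Control counts for Vpreb2 was 388 (107 to 3206). Ighm and Jchain, antibody genes, fell 2.27-fold and 1.80-fold. Immunoglobulin V segments went both ways: Ighv1-20 and Igkv7-33 were at least 224-fold and at least 198-fold lower, and Ighv15-2 had a ratio of Control to 5-FU+Saline counts of 515 (176 to 2502), while Igkv8-19, Ighv6-6 and Igkv1-135 rose 4.26-fold, 4.66-fold and 4.34-fold.

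Of 14 stromal genes 12 rose and 2 fell (median 5.04, or 4.58 with genes of 3 counts or fewer in a group at their bound). Camera put the list higher (adjusted p = 1.14e-08, adjusted p = 0.0256 with an estimated correlation). Cxcl12, a chemokine of marrow stroma (6, 117168535 to 117181367), rose from 2.32 ± 0.384 to 127 ± 2.54 CPM and the matrix gene Sparc 40.1-fold, while Pdgfrb fell 4.404-fold and Postn 1.69-fold, the latter not called without Control replicate 3 (adjusted p = 0.0655). The fat hormone gene Adipoq had a ratio of 5-FU+Saline to Control counts of 162 (55.3 to 789.9), the collagen gene Col6a1 was at least 189-fold higher, and Igfbp5 rose from 0.123 ± 0.0894 to 37.7 ± 2.23 CPM. Amotl1 and Tnfrsf19 had such ratios of 231 (78.8 to 1123) and 229 (78.0 to 1112). Of 14 endothelial genes 11 rose and 2 fell (median 1.90, adjusted p = 0.00850, adjusted p = 0.0873 with an estimated correlation): Fabp4 and Stab2 rose 57.8-fold and 2.52-fold, while Pecam1 and Ephb4 fell 1.32-fold and 1.74-fold. Of 19 monocyte and macrophage genes 14 rose and 4 fell (median 1.06), but camera did not call the list (adjusted p = 0.154).

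Smaller shifts down passed camera at the preset correlation alone. Of 15 MHC class I genes 6 rose and 8 fell (6 and 9 adjusted over the list alone; median -0.18, adjusted p = 0.0160, 0.0826 with an estimated correlation), with H2-Q7 and H2-Q4 2.09-fold and 1.82-fold lower and the proteasome genes Psme2 and Psmb8 1.47-fold and 1.199-fold higher. Of 11 MHC class II genes 1 rose and 7 fell (median -0.37, adjusted p = 0.0482, 0.121 with an estimated correlation, 0.0829 with the stricter filter), with H2-Ob 3.35-fold and Cd74 1.40-fold lower and H2-DMb2 1.89-fold higher. Of 20 autophagy and lysosome genes 5 rose and 11 fell (median -0.15, adjusted p = 0.0261, 0.197 with an estimated correlation), with Ulk1, which starts autophagy, and Sqstm1 2.57-fold and 2.04-fold lower and the lysosomal genes Lamp1 and Hexa 1.33-fold and 1.35-fold higher. Of 20 cholesterol genes 2 rose and 11 fell (median -0.28, adjusted p = 0.0261, 0.181 with an estimated correlation), with Insig1 2.59-fold lower and Acat2 and Stard4 1.63-fold and 1.23-fold higher. Adjusted over the list alone, the gene counts of the other 21 lists called in this comparison equalled those over all genes tested. Under upper-quartile factors 4661 genes were higher and 6210 lower, and the median of all genes moved to -0.10 on the log2 scale. More genes were lower than higher by small margins with the stricter filter (4371 higher and 4398 lower), with limma-voom (5408 and 5456) and without 5-FU+FMT replicate 1 (5493 and 5516) or 2 (5521 and 5533).

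**Figure D2:**
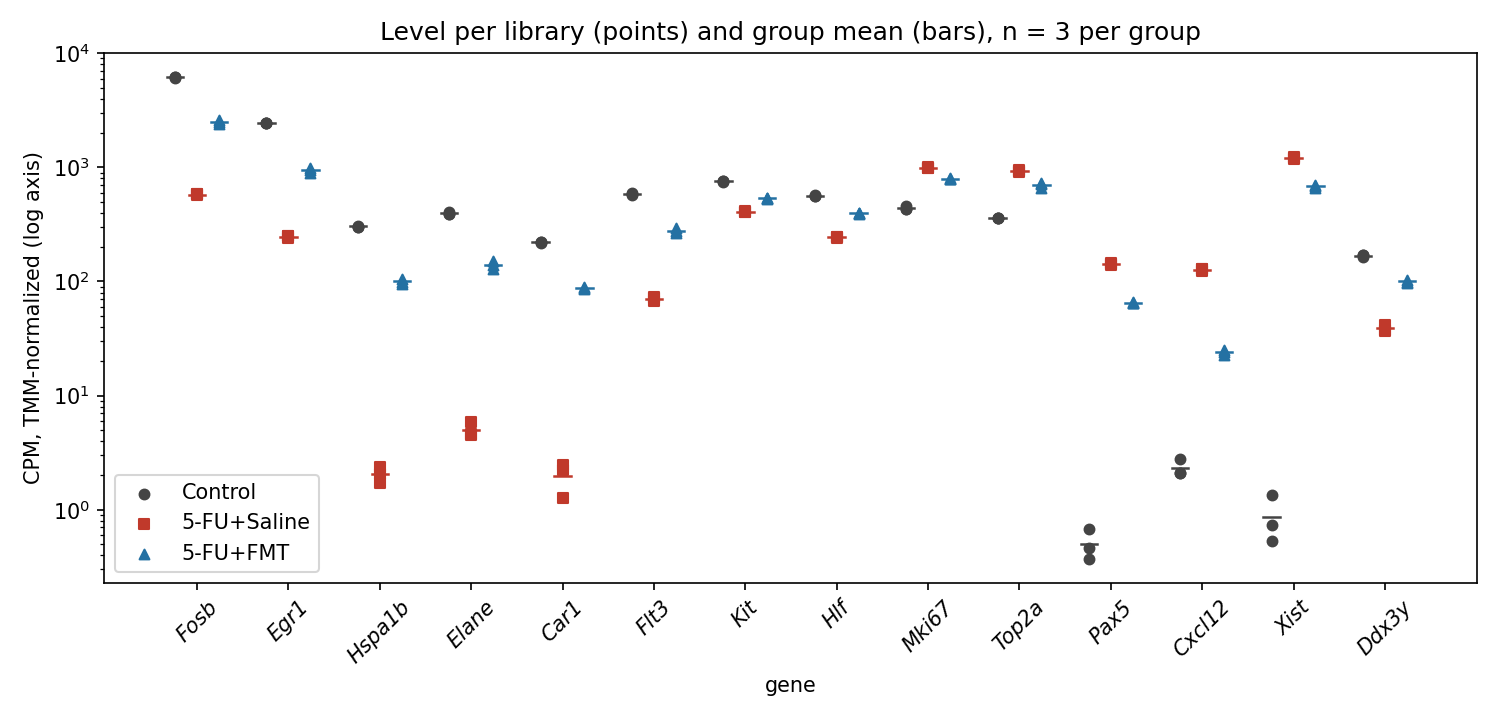
CPM of 14 genes on a log axis in each library (points) with the group mean (bars), n = 3 per group. In each of these genes the 5-FU+FMT libraries lie between Control and 5-FU+Saline, for example 2495 CPM for Fosb between 6149 and 577.

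The second comparison, 5-FU+FMT against 5-FU+Saline, sets FMT beside saline after 5-FU. Immediate early genes were higher with FMT: Fosb rose from 577 ± 9.28 to 2495 ± 110.0 CPM (4.32-fold), Klf6 from 161 ± 0.856 to 729.8 ± 33.0 (4.52-fold) and Jun from 404 ± 9.29 to 1730.0 ± 106 (4.28-fold; SD, n = 3). The erythroid gene Car1 and the granule gene Mpo were higher too, with Car1 rising from 1.99 ± 0.646 to 87.7 ± 1.71 CPM and Mpo from 29.9 ± 1.14 to 469 ± 27.9. Stromal and B lineage genes were lower, with Cxcl12 falling from 127 ± 2.54 to 24.2 ± 1.23 CPM and Pax5 from 142 ± 2.99 to 65.4 ± 1.04. Proliferation genes were slightly lower, such as Mki67, which fell 1.246-fold to 795 ± 4.14 CPM. Xist fell 1.76-fold and Ddx3y rose 2.56-fold in the same libraries, so these groups differed in sex-linked RNA as well as in FMT.

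In this comparison 2945 genes were higher and 3178 lower with FMT (36.9% of 16595), 586 and 267 of them by at least 2-fold and 94 and 11 by at least 8-fold. With upper-quartile factors 3136 were higher and 2972 lower, and with the stricter filter 2823 and 2777, so the side with more genes turned. CPM did not overlap for 46.3% of genes, against 10% by chance. Of the 38 lists, 11 were higher and 10 lower by camera, and 7 and 7 with an estimated correlation.

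All 20 immediate early genes rose (median 1.34, camera adjusted p = 7.17e-203, adjusted p = 0.000403 with an estimated correlation). Of 17 quiescence genes 10 rose and 5 fell (median 0.21, adjusted p = 5.97e-15), with Egr1 3.84-fold and Nr4a1 2.05-fold higher and Foxo1 1.39-fold lower. Of 22 NF-kB and inflammatory genes 9 rose and 2 fell (9 and 3 adjusted over the list alone; median 0.13, adjusted p = 3.69e-08): Ccl3 rose from 0.594 ± 0.247 to 38.8 ± 2.70 CPM and Nfkbiz 1.84-fold. Hspa1b rose 48.1-fold and Hspa1a 44.8-fold. Of 18 genes of the unfolded protein and integrated stress response 9 rose and 3 fell (10 and 3 adjusted over the list alone; median 0.16, adjusted p = 0.00808, adjusted p = 0.0938 with an estimated correlation), with Hspa5 1.63-fold and Atf4 1.36-fold higher and Pdia3 1.18-fold lower.

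Of 18 erythroid genes 13 rose and 1 fell (median 2.15, camera adjusted p = 2.39e-29): Ermap rose 53.8-fold, Car1 43.4-fold and Kel 32.2-fold, and Pklr, outside the list, rose 90.7-fold. The member that fell, Hbb-bt, was 1.21-fold lower (adjusted p = 0.0148), a call lost without 5-FU+FMT replicate 1 (0.113), 5-FU+FMT replicate 3 (0.0603), 5-FU+Saline replicate 2 (0.0770) or 5-FU+Saline replicate 3 (0.0636). Of 17 neutrophil genes 8 rose and 6 fell. The median was -0.09 and the mean 0.87, and camera put the list higher (adjusted p = 3.11e-33), with Elane 28.0-fold and Mpo 15.7-fold higher and Mmp9 2.58-fold and Ngp 1.87-fold lower. Of 13 mast cell and basophil genes 9 rose (11 adjusted over the list alone; median 1.102, adjusted p = 1.71e-06), such as Prss34 (18.2-fold) and Hdc, which makes histamine (4.58-fold). Of 16 multipotent and lymphoid-primed progenitor genes 10 rose and 4 fell (median 0.55, adjusted p = 2.17e-11), with Flt3 3.94-fold and Ctla2a 1.81-fold higher and Rag1 2.28-fold and Dntt 1.28-fold lower. Of 25 LT-HSC identity genes 12 rose and 4 fell (13 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.0217, adjusted p = 0.0979 with an estimated correlation), with Hlf 1.62-fold higher and Vwf 1.485-fold and Esam 1.24-fold lower. Kit rose 1.31-fold and Slamf1 fell 1.41-fold, Mecom stood at 154 and 147 CPM (adjusted p = 0.163), and Cdkn1a fell 1.202-fold. Cd48 fell 1.15-fold (adjusted p = 0.00815) but was not called without 5-FU+FMT replicate 2 (0.0518). Ly6a, at 118 and 108 CPM (adjusted p = 0.0226), was not called without 5-FU+FMT replicate 2 (0.121) or 3 (0.133) or without 5-FU+Saline replicate 1 (0.0563) or 2 (0.0790). Procr, at 61.3 and 67.7 CPM (adjusted p = 0.0318), was not called without 5-FU+FMT replicate 1 (0.0721), 2 (0.0655) or 3 (0.0721), without 5-FU+Saline replicate 1 (0.0618) or 2 (0.178), or with DESeq2 (0.0789), RLE factors (0.0580) or no filter (0.0571). Camera put the megakaryocyte list higher (adjusted p = 0.0259, 0.101 with an estimated correlation). Of its 18 genes 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.08), with Plek 4.89-fold higher and Selp, a platelet adhesion gene, 1.43-fold lower. The dendritic list was put higher too (camera adjusted p = 0.0180, 0.116 with an estimated correlation). Yet as many of its 11 genes fell as rose (3 and 3, or 3 higher and 4 lower adjusted over the list alone, median 0.11). It includes Flt3, which is also in the progenitor list.

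All 24 mitosis genes fell (median -0.36, camera adjusted p = 1.51e-15), as did 23 of 24 DNA replication genes (median -0.32, adjusted p = 2.78e-14), 19 of 25 DNA repair genes (median -0.25, adjusted p = 0.000126) and 22 of 24 oxidative phosphorylation genes (24 adjusted over the list alone; median -0.25, adjusted p = 6.98e-08, adjusted p = 0.0749 with an estimated correlation). Examples are Top2a (1.32-fold), Uhrf1 (1.46-fold), Parp1 (1.254-fold) and Atp5b (1.246-fold). Of 17 glycolysis genes 2 rose and 12 fell (median -0.18, adjusted p = 0.000220), with Ldha 1.32-fold lower and Slc2a3 1.251-fold higher. Of 22 ribosome biogenesis genes 1 rose and 16 fell (1 and 18 adjusted over the list alone; median -0.18, adjusted p = 1.15e-05), with Cad 1.31-fold lower and Myc 1.16-fold higher.

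Of 17 B cell genes 3 rose and 13 fell (median -0.90, camera adjusted p = 2.32e-13), with Pax5, Igll1 and Ebf1 falling 2.17-fold, 2.19-fold and 2.39-fold and Ighm and Jchain rising 1.41-fold and 1.22-fold. Of 14 stromal genes 2 rose and 11 fell (2 and 12 adjusted over the list alone; median -1.61, adjusted p = 6.14e-11): Adipoq fell 7.36-fold (16, 23146536 to 23158028), Cxcl12 5.25-fold and Sparc 3.97-fold, while Pdgfrb rose 2.13-fold. Lpl and Fabp4, genes of fat handling, and Igfbp5 fell 5.62-fold, 4.95-fold and 4.85-fold. Of 14 endothelial genes 1 rose and 8 fell (median -0.58, adjusted p = 0.00497, adjusted p = 0.0629 with an estimated correlation), with Flt4 2.44-fold and Stab2 1.45-fold lower. Of 19 monocyte and macrophage genes 3 rose and 11 fell (median -0.87, adjusted p = 0.0259, 0.0907 with an estimated correlation, 0.0553 with the stricter filter), with Vcam1 and Mrc1 3.12-fold and 3.17-fold lower and Ly6c2 and Csf1r 3.82-fold and 1.78-fold higher. Among V segments, Ighv15-2 had a ratio of 5-FU+FMT to 5-FU+Saline counts of 347 (118 to 1685) and Ighv3-1 rose from 0.102 ± 0.135 to 11.3 ± 1.45 CPM, while Igkv8-19, Ighv6-6, Igkv1-135, Ighv1-5 and Igkv4-58 fell 6.60-fold, 5.84-fold, 5.68-fold, 5.32-fold and 4.94-fold. Adjusted over the list alone, the gene counts of the other 12 lists called in this comparison equalled those over all genes tested.

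The third comparison, 5-FU+FMT against Control, asks how far cells exposed to 5-FU and FMT differed from untreated ones. Immediate early genes stayed below Control, with Fosb 2.47-fold, Egr1 2.58-fold and Jun 2.32-fold lower. Proliferation genes stayed above it, with Mki67 1.80-fold and Top2a 1.95-fold higher. Pax5 was at 65.4 ± 1.04 CPM against 0.501 ± 0.154 in Control and Igll1 at 68.1 ± 7.41 against 0.308 ± 0.221 (SD, n = 3). Xist was higher as well, and Ddx3y and Eif2s3y were 1.69-fold and 1.64-fold lower.

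Here 4151 genes were higher and 3584 lower (46.6% of 16595), 578 and 531 of them by at least 2-fold and 130 and 1 by at least 8-fold. The share of higher genes among those called, 53.7%, turned to 42.1% (3315 higher and 4559 lower) with upper-quartile factors. CPM did not overlap for 52.7% of genes, against 10% by chance, and of the 38 lists 10 were higher and 12 lower by camera, 7 and 9 with an estimated correlation.

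All 24 mitosis genes (median 0.89, camera adjusted p = 5.46e-54) and all 24 DNA replication genes rose (median 0.59, adjusted p = 2.52e-25), such as Ccnb1 (2.43-fold) and Rrm2 (2.02-fold). Of 25 DNA repair genes 21 rose (23 adjusted over the list alone; median 0.50, adjusted p = 2.08e-08), such as Parp1 (1.45-fold). Of 24 oxidative phosphorylation genes 21 rose (23 adjusted over the list alone; median 0.39, adjusted p = 3.87e-10, adjusted p = 0.0526 with an estimated correlation), such as Atp5b (1.42-fold). Of 17 glycolysis genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.21, adjusted p = 1.87e-05), such as Ldha (1.55-fold), and of 22 ribosome biogenesis genes 19 rose and 2 fell (20 and 2 adjusted over the list alone; median 0.26, adjusted p = 7.83e-06), such as Npm1 (1.35-fold). Fatty acid oxidation, which camera did not call in the other comparisons (15 genes higher and 3 lower, adjusted p = 0.0780, and 2 and 7, adjusted p = 0.296), had 14 of 21 genes higher and 1 lower (median 0.20, adjusted p = 0.0407, adjusted p = 0.289 with an estimated correlation), with Hadhb 1.41-fold and Cpt1a 1.21-fold higher. That call was lost without Control replicate 3 (0.0558), with upper-quartile factors (0.0644) and with the stricter filter (0.110).

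Of 17 B cell genes 13 rose and 3 fell (median 2.19, camera adjusted p = 5.98e-38), with Vpreb1 and Ebf1 at 47.0 ± 3.51 and 28.0 ± 5.01 CPM and Ighm 1.62-fold lower. Of 14 stromal genes 12 rose and 1 fell (median 3.36, or 3.21 with genes of 3 counts or fewer in a group at their bound; adjusted p = 2.07e-07), with Cxcl12 10.5-fold and Sparc 10.1-fold higher and Pdgfrb 2.07-fold lower. Of 14 endothelial genes 9 rose and 2 fell (median 1.05, adjusted p = 0.0170, 0.0879 with an estimated correlation, 0.0529 with the stricter filter). Gfra2 and Akap12 rose from 0.221 and 1.02 to 17.3 and 32.9 CPM, and the V segments Igkv3-1 and Ighv1-47 from 0.111 and 0.310 to 12.4 and 20.01 CPM. All 20 immediate early genes fell (median -1.19, adjusted p = 9.88e-117). Hspa1b and Hspa1a fell 3.04-fold and 2.93-fold.

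Of 18 erythroid genes 1 rose and 14 fell (1 and 15 adjusted over the list alone; median -1.13, camera adjusted p = 2.77e-09), with Car1 2.52-fold and Slc4a1 3.09-fold lower. Of 17 neutrophil genes 5 rose and 7 fell (6 and 7 adjusted over the list alone; adjusted p = 2.08e-08): the median was 0.10 and the mean 0.35, while camera put it lower. Mpo and Elane fell 2.72-fold and 2.84-fold and Ltf rose 25.5-fold, from 0.200 to 4.94 CPM. Of 16 multipotent and lymphoid-primed progenitor genes 3 rose and 11 fell (3 and 12 adjusted over the list alone; median -0.47, mean 0.01, adjusted p = 3.5e-07), with Flt3 2.09-fold lower. Also lower were lists of quiescence (2 up and 11 down of 17, median -0.26, adjusted p = 7.94e-13), NF-kB and inflammation (4 and 10 of 22, median -0.17, adjusted p = 1.52e-06), the unfolded protein response (1 and 14 of 18, 2 and 14 adjusted over the list alone, median -0.24, adjusted p = 6.94e-07), MHC class I (5 and 8 of 15, median -0.14, adjusted p = 0.00191) and MHC class II (8 of 11 down, or 1 up and 8 down adjusted over the list alone, median -0.41, adjusted p = 0.00310), with Ccl3 2.79-fold, Hspa5 1.77-fold and Cd74 1.38-fold lower. Autophagy (3 and 10 of 20, median -0.14, adjusted p = 0.0132, 0.135 with an estimated correlation), cholesterol (2 and 7 of 20, median -0.18, adjusted p = 0.00538, 0.0879 with an estimated correlation) and p53 targets (3 and 9 of 23, median -0.11, adjusted p = 0.0425, 0.140 with an estimated correlation) were lower too, with Insig1 1.67-fold, Cdkn1a 1.198-fold and the p53 target Trp53inp1 1.40-fold lower. The p53 call was lost without Control replicate 2 (0.0693) and without 5-FU+FMT replicate 3 (0.0656). Hlf fell 1.43-fold and Kit 1.40-fold, while Slamf1 rose 2.94-fold, Cd48 1.52-fold and Mecom 1.249-fold. Ly6a, at 97.2 and 108 CPM (adjusted p = 0.00772), was not called without 5-FU+FMT replicate 1 (0.143), Control replicate 2 (0.101) or with upper-quartile factors (0.161). Procr, at 74.4 and 67.7 CPM (adjusted p = 0.0391), was not called without 5-FU+FMT replicate 1 (0.0833), 2 (0.0911) or 3 (0.0849), without 5-FU+Saline replicate 1 (0.05), without Control replicate 1 (0.174) or 2 (0.0886), or with DESeq2 (0.0533) or no filter (0.296). Epha1 and Iqcn fell 3.15-fold and 3.56-fold, as did the V segments Igkv7-33 (3.83-fold), Igkv8-16 (3.66-fold), Ighv12-3 (3.27-fold) and Igkv1-133 (3.21-fold). Adjusted over the list alone, the gene counts of the other 13 lists called in this comparison equalled those over all genes tested.

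**Figure D3:**
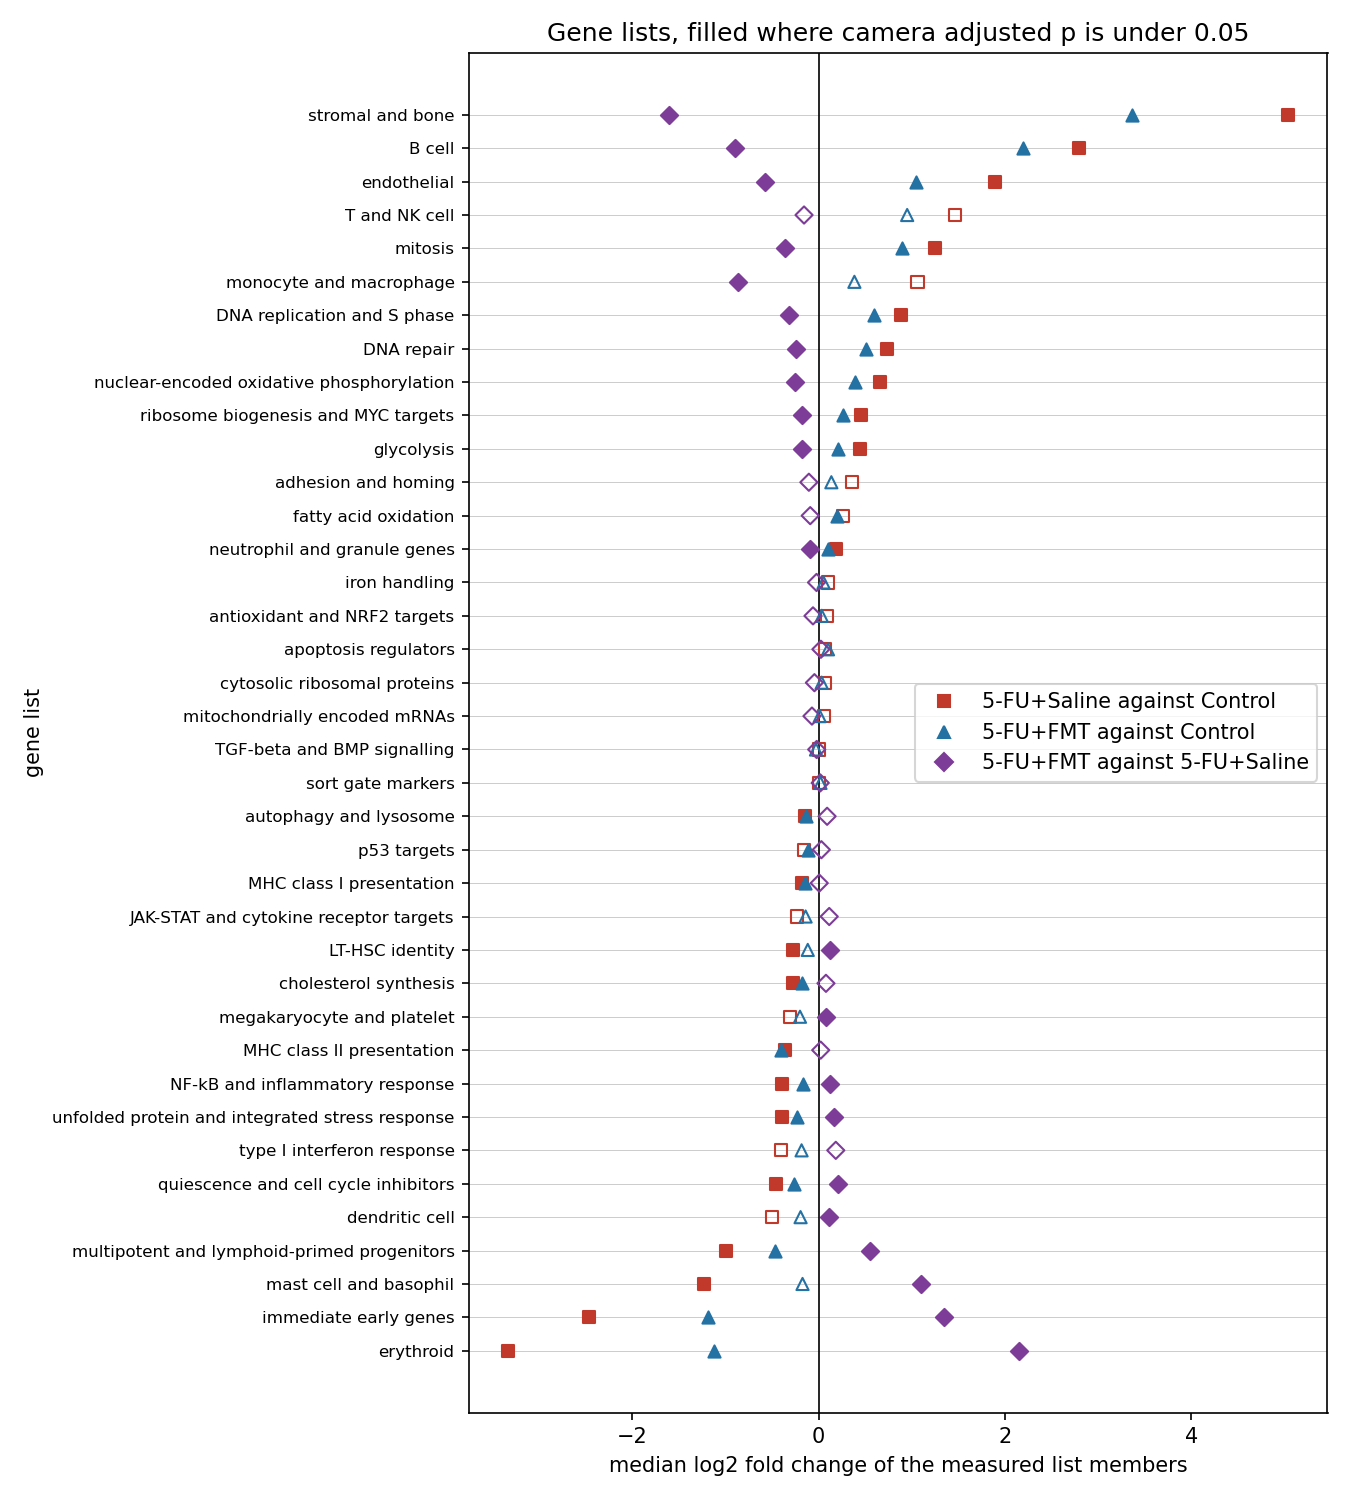
Median log2 fold change of the measured members of each gene list in the 3 comparisons, filled where camera's adjusted p is under 0.05. The stromal list lies at 5.04 and the erythroid list at -3.33 in 5-FU+Saline against Control, and both lie on the other side of 0 in 5-FU+FMT against 5-FU+Saline (-1.61 and 2.15).

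For genes changed at least 2-fold after 5-FU and saline, with 5 CPM or more in either group, the level in 5-FU+FMT nearly always lay between those of the other groups. On a scale with Control at 0 and 5-FU+Saline at 1, the 242 genes at least 4-fold lower after 5-FU and saline had a median position of 0.629 (95% bootstrap interval over genes 0.616 to 0.643). The 174 genes at least 4-fold higher had a median position of 0.460 (0.444 to 0.491). At 2-fold the medians were 0.628 (0.621 to 0.633) for lower and 0.539 (0.526 to 0.550) for higher genes. Xist and the 4 Y-linked genes lay at 0.416 to 0.568. Of the genes changed at least 2-fold, 98.8% of 854 lower and 98.02% of 555 higher ones lay between Control and 5-FU+Saline.

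**Figure D4:**
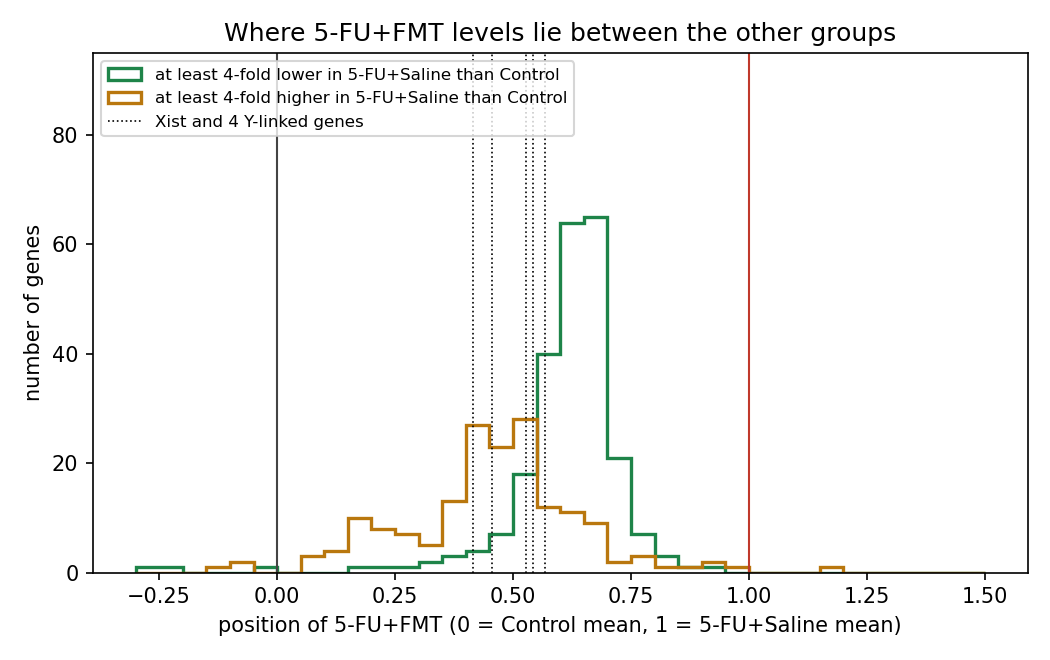
Number of genes at each position of the 5-FU+FMT mean between the Control mean (0) and the 5-FU+Saline mean (1), for genes at least 4-fold lower or higher in 5-FU+Saline, with 5 sex-linked genes as dotted lines. Lower genes have a median of 0.629 and higher genes of 0.460.

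With genes called on 5-FU+Saline libraries other than the one measured, 91.1% ± 0.416 of them (SD, n = 3 left-out libraries) moved in 5-FU+FMT the opposite way to 5-FU and saline, where 50% would move so with no difference between these groups, if the left-out library is independent of the others. If the libraries of a group are repeats of 1 pool, that share may exceed 50% with no effect of FMT. The slope of the FMT change on the 5-FU change was -0.372, and -0.446 with the stricter filter, so its size depends on the filter. Against Control, 4013 genes were higher and 3405 lower in both treated groups, where independent lists would share 1361 and 1172, and 99.6% of the 7445 genes called in both moved the same way. The correlation of both sets of fold changes across genes, which are not independent replicates, was 0.865, against 0.513 on average (highest 0.529) in simulations with no true change against the same controls. Their covariance was 0.694, against 0.0238 in the simulations. The simulated libraries were drawn independently with the spread seen within groups. If each group is 1 pool, the simulations leave out differences between pools, and their values are too low a reference. With 3 Control libraries the controls cannot be split between both comparisons with more than 1 library on a side, so part of the shared change may come from the controls they share.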

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

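The tests chosen after the data were seen are glmTreat and the counts without immunoglobulin and sex chromosome genes; all other alternatives were fixed in advance. Testing for a change above 1.5-fold with glmTreat left 1535 genes higher and 1945 lower in 5-FU+Saline against Control, 437 and 177 in 5-FU+FMT against 5-FU+Saline, and 520.0 and 389 in 5-FU+FMT against Control, fewer by construction. Lists called in 5-FU+Saline against Control numbered 22, and 12 with an estimated correlation. Genes shared against Control numbered 7418, and 1011 among genes changed at least 2-fold, fewer by construction. Opposite movement was 91.1%, and 91.5% for genes changed at least 2-fold, 90.5% with upper-quartile factors and 92.2% with the stricter filter; the cause of these shifts was not tested.

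With a replicate block, 5434 genes were higher and 5413 lower in the first comparison, 2982 and 3211 in the second, and 4157 and 3560.0 in the third, with 10796, 6080.0 and 7647 genes called both with and without it. Without immunoglobulin and sex chromosome genes the counts were 5173 and 5147, 2744 and 3020.0, and 3942 and 3372. Leaving out each library in turn gave 5174 to 5534 genes higher and 5124 to 5533 lower in the first comparison, 2536 to 2967 and 2755 to 3244 in the second, and 3800.0 to 4154 and 3112 to 3571 in the third, with 22 to 23, 21 to 23 and 21 to 23 lists called. Of 10196 values of the single genes followed under all alternatives, 9876 kept their direction and side of the threshold, 307 lost their call (212 of them with glmTreat, which asks for a change above 1.5-fold), 13 gained one and 0 turned direction, and no list turned direction by camera. Some lists gained a call from camera (adjusted p in brackets). In 5-FU+FMT against 5-FU+Saline, the antioxidant list was called with the replicate block (0.0486), without Control replicate 1 (0.0469), 2 (0.0474) or 3 (0.0474), without 5-FU+Saline replicate 2 (0.0314) or 3 (0.0306) and without 5-FU+FMT replicate 1 (0.0292), and ribosomal proteins without 5-FU+Saline replicate 2 (0.0222) or 3 (0.0326) or 5-FU+FMT replicate 1 (0.0053). In 5-FU+Saline against Control, ribosomal proteins were called without 5-FU+Saline replicate 2 (0.0460), megakaryocyte genes without Control replicate 2 (0.0460), and dendritic genes with the stricter filter (0.0371), without Control replicate 3 (0.0480) and without 5-FU+FMT replicate 3 (0.0497). In 5-FU+FMT against Control, ribosomal proteins were called without 5-FU+FMT replicate 2 (0.0192). The cause was not tested. In simulations at these depths with 3 libraries per group, at most 12% of 1.1-fold changes were called.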

Other observations

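The tests of counting noise, of mixed RNA, of male and female shares, of lymphoid priming and of other cell types were chosen only after the result was seen, and those of other splits and of pooled repeats before. Some uncalled gene lists held strong single changes, in 4 of the 5 lists given here at least 2-fold in both directions. In TGF-beta and BMP signalling (19 genes, 6 higher and 8 lower, or 7 and 8 adjusted over the list alone; camera adjusted p = 0.805 in 5-FU+Saline against Control), the receptor Tgfbr3 and the ligand Tgfb1 rose 3.42-fold and 2.32-fold, while Smad7 and Skil, brakes on the pathway, fell 4.53-fold and 3.23-fold, from 175 ± 8.16 to 38.7 ± 4.43 and from 214 ± 9.51 to 66.3 ± 0.812 CPM (SD, n = 3). In JAK-STAT targets (20 genes, 5 and 11; adjusted p = 0.387), the feedback gene Socs2 and the survival gene Bcl2l1 rose 5.31-fold and 2.86-fold, while the cytokine receptor Csf2ra and the feedback gene Socs3 fell 2.27-fold and 1.80-fold. In apoptosis regulators (18 genes, 8 and 5; adjusted p = 0.805), the survival gene Mcl1 fell from 1024 ± 4.52 to 438 ± 10.2 CPM and the death gene Bcl2l11 2.76-fold, while Bak1, a death gene, rose 1.91-fold. In adhesion and homing (21 genes, 14 and 5; adjusted p = 0.177), the integrin Itgb2 rose 2.26-fold and Rac1 1.602-fold, while Cd34 and Alcam fell 2.04-fold and 3.04-fold. In iron handling (21 genes, 8 and 8; adjusted p = 0.805), Hmox1, which breaks down heme, rose 4.96-fold and the ferritin genes Ftl1 and Fth1 fell 1.33-fold and 1.27-fold. With FMT, Smad7, Skil, Mcl1, Alcam and Cd34 rose 2.22-fold, 1.64-fold, 1.48-fold, 1.92-fold and 1.51-fold against 5-FU+Saline, and Tgfbr3, Socs2, Bcl2l1 and Hmox1 fell 1.46-fold, 1.58-fold, 1.489-fold and 2.70-fold.

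Camera called none of these lists, nor the interferon, antioxidant, T and NK cell, mitochondrially encoded, ribosomal protein or sort gate lists, in any comparison at the preset correlation. In 5-FU+Saline against Control their adjusted p-values were 0.270 for interferon (4 higher and 13 lower of 23), 0.124 for antioxidant (10 and 4 of 21), 0.235 for T and NK cell (9 and 4 of 15), 0.184 for mitochondrially encoded (6 and 1 of 12) and 0.0824 for ribosomal protein genes (44 and 14 of 86). A small set of genes left the range of both other groups in 5-FU+FMT: 44 genes were higher than in both and 61 lower, and of the 21 and 19 beyond 1.5-fold, 14 and 11 were immunoglobulin genes. Of the mast cell and basophil list, 2 genes were higher and 5 lower (2 and 6 adjusted over the list alone) of 13 in 5-FU+FMT against Control (camera adjusted p = 0.299), with the proteases Prss34 and Mcpt8 2.53-fold and 2.49-fold lower. Other mast cell proteases were above both groups, chosen after their values were seen: Tpsb2 had 1.65, 4.803 and 10.2 CPM in Control, 5-FU+Saline and 5-FU+FMT, Cma1 1.87, 4.37 and 6.74, and Mcpt4 0.563, 3.50 and 6.12, the last not called in 5-FU+FMT against 5-FU+Saline without 5-FU+FMT replicate 1 (adjusted p = 0.0574). The V segment Ighv1-37, also chosen so, was at least 89.4-fold higher in 5-FU+FMT than in 5-FU+Saline.

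For each comparison only 10 splits of the 6 libraries exist, too few for a share under 0.05: 1 of 10 splits, the real one, gave as many called genes, with 10872, 6123 and 7735 genes against at most 0, 0 and 1 in the other splits.

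Libraries of 1 group differed little. Between libraries of a group, 147 immunoglobulin V segment genes had 1.102 times the SD of genes matched on level (95% interval 1.06 to 1.17), against 3.36 times between groups. Mice use V segments differently, so this is consistent with the 3 libraries of a group being repeats of 1 pool of cells or RNA. Counting noise alone was excluded, since the lowest chi-square per degree of freedom within groups was 2.15. If each group is 1 pool, treatment and pool vary together in these libraries. Levels of Xist and Y-linked genes vary with treatment in either case.

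The 5-FU+FMT group may lie between the others through a mixture of cells or through an effect of FMT on each cell. RNA of both other groups in a single proportion was excluded, since median positions of lower and higher genes differed by 0.169 for genes changed at least 4-fold, and lay at 0.628 (0.621 to 0.633) and 0.539 (0.526 to 0.550) at 2-fold. Control RNA in the 5-FU+Saline libraries was excluded as the source of their Y-linked reads, since it would leave no gene below their share of Control, while 35 of the 2343 genes with at least 100 CPM in Control, outside chromosome Y and the immunoglobulin genes, lay in 5-FU+Saline below the lowest Y-linked share of 23.1%. Whether different shares of male and female cells set the position of the genes that fell was not decided. Their median of 0.629 (0.616 to 0.643) lies above the range of 5 sex-linked genes (0.416 to 0.568). It also lies above the 95% interval of the mean of these genes (0.422 to 0.581), but inside the limits for 1 further gene (0.308 to 0.695). These were 3 rules tried after the values were seen, the interval of the mean last, and that interval treats 5 genes as replicates. Such shares also stay open for the genes that rose, at 0.460, and an effect of FMT itself for both sets. Of the first tests, 2 were replaced after their results were seen. In 1 of them Xist stood at 56.8% of its 5-FU+Saline level where Y-linked genes predicted 48.7% (1.17 times). The other was of Control RNA on genes picked for their fall.

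B lineage and stromal genes rose together after 5-FU. Most monocyte and macrophage genes rose as well (14 of 19 higher and 4 lower, median 1.06, 0.314 to 3.36). Camera did not call that list (adjusted p = 0.154). A lower share of stem cells raising all other types alike was excluded, since the erythroid median was -3.33 (-5.34 to -1.47), while lymphoid priming of the stem cells stays open: the multipotent and lymphoid-primed list had a median of -0.999 (-1.32 to -0.114), but Rag1 and Rag2 rose 34.4-fold and 11.03-fold and Dntt 1.24-fold, and a first test that left out members that rose was replaced. Cells of the B lineage are a candidate source that stays open. The 12 list members taken without immunoglobulin genes, Jchain and Cr2 had an SD of 0.225 (0.121 to 0.286) of their log2 ratio with FMT. This misses the limit set for it from the 0.400 of 474 other genes that rose. Igll1 and Pax5 stood at 149 and 142 CPM in 5-FU+Saline, and 7 of 17 B cell genes at 5 CPM or more in Control. Ighm and Jchain went the other way, from 4119 and 2694 CPM in Control to 1813 and 1497. Their RNA was thus already high in Control, where Igll1 and Pax5 were at 0.308 and 0.501 CPM. Its fall therefore does not decide the source of the genes that rose. A first count, 13 of 13 members at least 2-fold higher, was replaced since it could not separate causes. A single kind of stromal cell stays open too, at an SD of 0.625 (0.315 to 0.809; 9 genes), with Cxcl12 and Sparc at 127 and 34.1 CPM and 2 of 14 stromal genes at 5 CPM or more in Control; its rule was changed, to count the interval, after the first outcome excluded it. Neither the B cell nor the stromal list shares a gene with another. The lineage-negative and c-Kit-positive gates are meant to leave both kinds of cell out, though the labels do not list the lineage antibodies.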
